A study of Homo sapiens with 6 samples.

How the data were processed

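RNA sequencing of total RNA was available for 6 NCI-H1299 libraries, 3 from control cells and 3 from IGF2BP3 knockout cells, grouped by their titles. Per the labels' protocols, reads were trimmed with Cutadapt and aligned with HISAT2, and transcripts were reconstructed and genes quantified with StringTie. The submitters' processing notes name HISAT2 2.0.4, StringTie 1.3.4d, edgeR and the build GRCh38; the version of Cutadapt, the annotation release and whether counting used the strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart. The table the authors deposited gives whole read counts per gene and library, with no normalization, next to FPKM values, which the authors scaled per kilobase of gene and for the number of reads.

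The table held 35784 Ensembl gene identifiers, of which 35754 were found in the reference name table and 1802 had a count of 0 in all 6 libraries. A symbol was lacking for 9368 identifiers, and 411 rows carried a repeated symbol, for which the row with the highest count was used. Gene coordinates and symbols are those of the table. Totals ran from 67674223 to 80810319 counts. Counts from 4 to 10 were even in 69.9% to 71.0% of cases, against 49.5% to 50.1% of counts above 100, so that both mates of a pair appear to have been counted. The number of independent fragments is therefore smaller than the counts, and floors cover counting error only. Among 11637 genes with counts of at least 200, the ratio of FPKM to count per library was constant within 0.02 on the log2 scale for 99.7%. No pair of libraries in a group agreed within sampling noise, the smallest chi-square per degree of freedom being 12.2. All were therefore kept as separate libraries, which does not show that they came from separate cultures.

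From the counts, genes were filtered with filterByExpr (minimum count 10, minimum total 15), normalized by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with genotype as the only term and all 6 libraries in the fit. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over 20134 genes. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM are counts scaled by the total of each library, adjusted by TMM. The 36 gene lists and the 23 chromosomes other than Y with at least 5 tested members were compared with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. The counts of 1 list that did not pass are not reported here. Lists, tests and the rule for named genes were fixed before the data were examined. That rule named the IGF2BP family, the 12 largest rises and 12 largest falls among called genes with an official symbol, at least 5 CPM in the higher group and groups that do not overlap, and in each list up to 4 called members with the smallest adjusted p or, where none was called, up to 2 with the smallest p. The list of rises outside the Y chromosome was added after the values were seen.

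The fits were tested on simulated counts for the comparison of IGF2BP3 knockout with control. They used real means and library sizes and the trend of dispersion on level, without the scatter of single genes around it. Of 200 changed genes among 19372, the edgeR fit recovered 12% of those changed 1.5-fold and 68% of those changed 3-fold, with 1.1% of calls false. DESeq2 recovered 24% and 72% with 24.5% of calls false. A list of 30 genes shifted 1.5-fold was called and 0 of 20 unchanged lists were. Genes were drawn independently and these lists held random genes, so false calls among lists whose members move together were not tested.

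Alternatives were no filter, a mean count of at least 100, DESeq2-type size factors, quantile normalization with limma-voom, DESeq2 1.42.0, a minimum fold of 1.5, the replicate number as a block, and leaving out each library. Added after the data were seen were limma on log2 of FPKM plus a pseudocount of 1 for genes with a mean of at least 1 FPKM, limma-voom with TMM, and a fit without the genes of chromosomes 16 and Y. For windows along chromosomes, 50 neighbouring tested genes were taken at a time.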

Results

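Messenger levels were measured by RNA sequencing of total RNA in NCI-H1299, a human non-small cell lung carcinoma line that the labels class as lung adenocarcinoma cells. IGF2BP3 is an RNA-binding protein of the insulin-like growth factor 2 mRNA-binding family, known as a reader of N6-methyladenosine and as an oncofetal protein. The gene had been cut with a lentiviral CRISPR vector, and cells had been selected with puromycin and grown on as single-cell colonies. There were 6 libraries in 2 groups, 3 from cells carrying a control vector and 3 from IGF2BP3 knockout cells. The labels do not say which colony each library came from, nor whether the replicates of a group were separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical. The control libraries held 75841196, 69943874 and 69973174 counts. The knockout libraries held 80810319, 67674223 and 74162440. A count of 3, taken as the floor, corresponded to between 0.0371 and 0.0443 CPM (counts scaled to a common library total), for counting error only. Levels below are means in CPM ± SD with n = 3 per group, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

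The first question was whether the message of the targeted gene differed between the groups. IGF2BP3 (ENSG00000136231, GRCh38 chromosome 7 from 23310209 to 23470491, minus strand, protein coding) was at 58.8, 51.6 and 54.1 CPM in the control libraries and at 39.9, 25 and 22.6 CPM in the knockout libraries. Its mean fell from 54.8 ± 3.63 to 29.2 ± 9.35 CPM, which was 53.2% of the control level (log2 fold change -0.91, SE 0.20, adjusted p = 0.017). The message was thus lower in each of the 3 knockout libraries and was still detected in all of them, with the highest of the 3 values in replicate 1. A gene-level count does not show whether the remaining message carries an edit. The direction held with each library left out, but the adjusted p was 0.067 without control replicate 1, 0.05 without control replicate 2, 0.056 without control replicate 3 and 0.065 without knockout replicate 2, none of them past the threshold. Against a minimum fold of 1.5 the adjusted p was 0.25, and over all alternatives it ranged from 1.3e-04 to 0.25. Of the other members of the family, IGF2BP2 (ENSG00000073792, chromosome 3 from 185643130 to 185825042) rose from 17.8 ± 0.395 to 32.3 ± 4.18 CPM (log2 fold change 0.86, SE 0.11, adjusted p = 0.0018). IGF2BP1 was at 194 ± 6.21 CPM in the controls and 188 ± 20.1 CPM in the knockout libraries, a difference within the spread (adjusted p = 0.81).

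**Figure D1:**
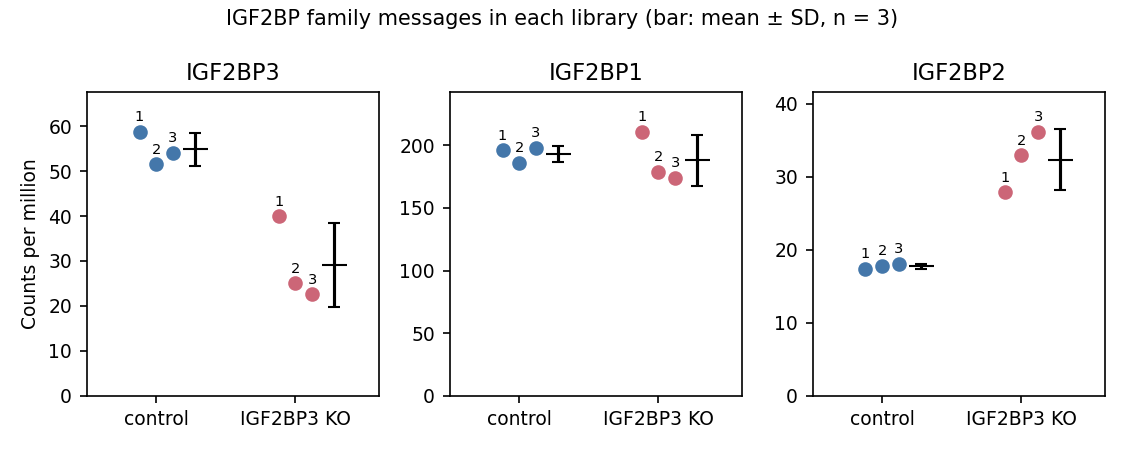
CPM of the IGF2BP family messages in each library, with numbers marking the replicates of each group and bars giving mean ± SD (n = 3). IGF2BP3 lay between 51.6 and 58.8 CPM in the controls and between 22.6 and 39.9 CPM in the knockout libraries, and IGF2BP2 was higher in all 3 knockout libraries.

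The comparison of all genes asked which messages differ between IGF2BP3 knockout and control cells. The 12 largest falls lay between 47.7-fold and 113-fold. MUC5AC, a gel-forming airway mucin, fell from 606 ± 8.05 to 7.3 ± 2.05 CPM (log2 fold change -6.37, SE 0.21, adjusted p = 4.3e-06). KRT19, a keratin of simple epithelia, fell from 64.1 ± 4.79 to 0.645 ± 0.112 CPM (log2 fold change -6.64, SE 0.15, adjusted p = 1.8e-06). The carcinoembryonic adhesion molecule CEACAM6 fell from 173 ± 35.3 to 1.82 ± 0.216 CPM and its relative CEACAM5 from 11.2 ± 3.73 to 0.0969 ± 0.0436 CPM. Reads of the family's similar sequences may have been split between its members. GRIK2, a kainate receptor subunit, COL11A1, a fibrillar collagen chain, and the cation channel TRPM2 fell with log2 fold changes of -6.18, -5.95 and -5.89. PABPC4L, the catenin CTNND2 and the arsenic methyltransferase AS3MT fell with log2 fold changes of -6.31, -5.90 and -5.58. The UDP-glucuronosyltransferase UGT1A9 fell from 235 ± 6.35 to 4.09 ± 0.809 CPM. UGT1A7 fell from 8.32 ± 4.98 to 0.0811 ± 0.0382 CPM. The counts of both UGT1A9 and UGT1A7 are uncertain because the transcripts of their locus share exons.

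Of the 12 largest rises, 9 were genes of the Y chromosome, with log2 fold changes between 4.92 and 6.39. On that chromosome 20 of the 25 tested genes rose and 0 fell, the median of the 20 going from 0.029 CPM, below the floor, to 2.91 CPM. The remaining 3 were SLC1A3, a glial-type glutamate transporter, from 1.35 ± 0.662 to 31.5 ± 21.3 CPM (log2 fold change 4.55, SE 0.74, adjusted p = 0.005), RNF212 and GABRA3. RNF212 rose from 0.391 ± 0.1 to 6.59 ± 2.97 CPM, and the GABA-A receptor subunit GABRA3 rose from 0.62 ± 0.118 to 7.8 ± 0.593 CPM. A list of the 12 largest rises outside the Y chromosome was drawn up after its values were seen. It added ANK1, an ankyrin of the membrane skeleton, which rose from 4.25 ± 0.39 to 53.3 ± 5.56 CPM (log2 fold change 3.65, SE 0.12, adjusted p = 4.3e-06). It also added ZSCAN18, TMEM178B, MARK1, TEX15, ZNF850, MAGEA6, CA8 and ATRNL1, with log2 fold changes from 3.03 for ATRNL1 to 3.50 for ZSCAN18.

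In total 3963 of 20134 tested genes (19.7%) passed the threshold, of which 1652 rose and 2311 fell, so that 58.3% of the calls were lower in the knockout. This share was 57.5% with DESeq2-type size factors and 59.4% with limma-voom and TMM, but 49.6% with limma-voom after quantile normalization (2360 up and 2322 down). On FPKM, where the filter and the test also differed, it was 49.7% (1818 up and 1793 down). At least 2-fold changes were called for 481 rises and 943 falls. The groups did not overlap for 41.3% of the tested genes, against 10% by chance, and the biological coefficient of variation was 25%. Knockout replicate 1 stood apart from the other 2 knockout libraries on the second principal component (75.7 against -46.3 and -26.9). Control replicate 3 differed more from the other 2 controls (chi-square per degree of freedom 45.3 and 45.2) than these did from each other (12.2). The count of calls was 2183 without control replicate 1, 2266 without control replicate 2, 2497 without knockout replicate 2 and 2569 without knockout replicate 3. The rises alone also numbered 1091 without control replicate 3, and 1864 genes were called in the same direction in the fit of all libraries and in each fit that left out 1.

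**Figure D2:**
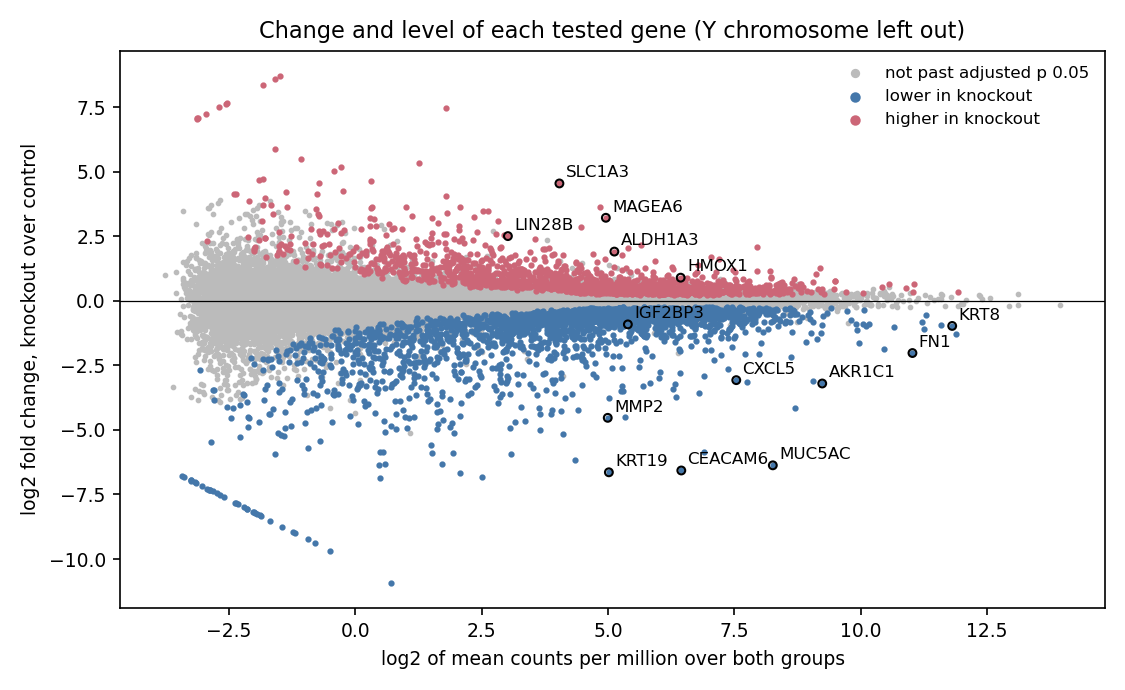
Each tested gene outside the Y chromosome by its log2 mean CPM over both groups (x axis) and its log2 fold change, knockout over control (y axis); coloured points passed an adjusted p of 0.05. Genes along the outer diagonals had counts near 0 in 1 group, where the fitted fold depends on the prior count, while KRT19, CEACAM6 and MUC5AC fell at well-covered levels with log2 fold changes between -6.64 and -6.37.

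Lists of genes with related functions, fixed before the data were examined, were then compared as groups with camera at a preset correlation of 0.01. Of 36 lists, 15 passed, 10 lower and 5 higher in the knockout. With an estimated correlation 0 passed, 4 having an unadjusted p under 0.05, so each p of that kind is given beside its list. That option also uses fewer degrees of freedom, which raises p-values by itself, so a lost call need not mean correlated members. Among epithelial markers 5 of 21 tested members fell, 1 rose and 15 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 1.5e-04; adjusted p = 0.2 with an estimated correlation). Next to KRT19, KRT8 fell from 4750 ± 151 to 2430 ± 260 CPM and its partner KRT18 from 3060 ± 165 to 1710 ± 30.5 CPM. Both have many processed pseudogenes that can share reads. The median log2 ratio of the list to the controls was -0.35, -0.07 and -0.27 in knockout replicates 1, 2 and 3. The tight-junction protein OCLN rose from 8.11 ± 1.05 to 24 ± 6.94 CPM. Of the 21 tested members of this list, 4 lie on chromosome 16, whose genes were lower as a whole.

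Mesenchymal markers were lower as well, with 8 of 21 members down, 3 up and 10 not past the threshold. They were 11 down and 4 up as adjusted over the list alone (camera adjusted p = 3.2e-09; adjusted p = 0.075 with an estimated correlation). The gelatinase MMP2, which lies on chromosome 16, fell from 61.1 ± 2.95 to 2.64 ± 0.269 CPM (log2 fold change -4.53, SE 0.11, adjusted p = 1.8e-06). Fibronectin FN1 fell from 3340 ± 217 to 823 ± 46.5 CPM, fibrillin FBN1 from 33.7 ± 1.18 to 7.73 ± 0.886 CPM and the calcium-binding protein S100A4 from 207 ± 6.36 to 55.3 ± 14.1 CPM. Integrins and matrix genes went both ways, 7 up and 8 down of 34 (9 and 8 as adjusted over the list alone). The set did not pass (camera adjusted p = 0.98), with a median and a mean below 0 and a test direction above it. In that list ITGB8 fell from 5.82 ± 0.508 to 0.29 ± 0.0275 CPM. The basement-membrane collagens COL4A1 and COL4A2 rose from 93.4 ± 3.38 to 182 ± 22.6 CPM and from 291 ± 9.18 to 528 ± 66.2 CPM.

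Of 12 tested genes of the lung epithelial lineage, 3 fell and 2 rose (4 and 3 as adjusted over the list alone), with a median log2 fold change of 0.00 and a mean of -0.08 (camera adjusted p = 0.037; adjusted p = 0.33 with an estimated correlation). Next to MUC5AC, the membrane mucin MUC1 fell from 6.3 ± 1.17 to 1.79 ± 0.459 CPM. The median log2 ratio of the list to the controls was -0.32 in knockout replicate 1, -0.06 in replicate 2 and 0.1 in replicate 3. FOXJ1, a regulator of motile cilia, rose from 0.0423 ± 0.0435 CPM, near the floor, to 1.59 ± 0.965 CPM. The set's call was lost with no filter on low counts (adjusted p = 0.46), with quantile normalization (adjusted p = 0.4) and with limma-voom (adjusted p = 0.44), within a range from 3.5e-04 to 0.46 over the 16 alternatives tested with camera.

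NRF2 targets, genes of the oxidative stress response, included 10 falls and 4 rises among 23 (11 and 4 as adjusted over the list alone; camera adjusted p = 2.2e-06; adjusted p = 0.1 with an estimated correlation). The glutathione peroxidase GPX2 fell from 206 ± 13 to 17.5 ± 1.42 CPM (log2 fold change -3.56, SE 0.10, adjusted p = 2.1e-06). The aldo-keto reductase AKR1C1 fell from 1090 ± 73.8 to 118 ± 30.9 CPM, with reads that its close copies in the family can share. The transporter ABCC3 fell from 1330 ± 22.9 to 614 ± 25 CPM. Haem oxygenase HMOX1 and the glutamate-cysteine ligase subunit GCLC, both on the same list, rose from 60.3 ± 0.835 to 113 ± 1.24 CPM and from 230 ± 10.2 to 327 ± 5.32 CPM. Drug transport and aldehyde metabolism genes did not pass camera as a set (3 up and 6 down of 19, 4 and 8 as adjusted over the list alone, camera adjusted p = 0.19). Fry's directional test, which does not compare a list with other genes, called them lower (adjusted p = 0.0027). In this list ALDH3A1 fell from 2160 ± 147 to 1070 ± 7.16 CPM and ALDH2 from 290 ± 20.9 to 126 ± 3.82 CPM. In contrast, ALDH1A3, a retinaldehyde dehydrogenase, rose from 14.7 ± 1.69 to 55.1 ± 2.08 CPM.

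Inflammatory and immune lists were lower in the knockout. Of 25 tested NF-kB targets and cytokines 13 fell and 1 rose, the same counts as adjusted over the list alone (camera adjusted p = 2.7e-08; adjusted p = 0.34 with an estimated correlation). All 14 were also called with each library left out. This held for 9 of the 14 calls among interferon-stimulated genes and 5 of the 11 in MHC class I antigen presentation, described next. The neutrophil-attracting chemokines CXCL1 and CXCL5 fell from 60.4 ± 13.7 to 4.4 ± 0.833 CPM and from 332 ± 74.5 to 39.5 ± 8.01 CPM. TNFAIP3, an inhibitor of NF-kB signalling that is itself induced by it, fell from 35.4 ± 4.02 to 13.9 ± 1.08 CPM. Of 36 interferon-stimulated genes 13 fell and 1 rose (18 and 1 as adjusted over the list alone; camera adjusted p = 1.7e-04; adjusted p = 0.34 with an estimated correlation). Among them IFITM3 went from 34.2 ± 3.04 to 7.83 ± 1.83 CPM and IFI44 from 6.51 ± 0.56 to 1.61 ± 0.0641 CPM. The median log2 ratio of this list to the controls was -0.67 in knockout replicate 1 and -0.42 and -0.31 in replicates 2 and 3. Of 18 genes of MHC class I antigen presentation 10 fell and 1 rose (12 and 1 as adjusted over the list alone; camera adjusted p = 0.0017; adjusted p = 0.33 with an estimated correlation). HLA-E fell from 115 ± 7 to 77.7 ± 3.05 CPM and the peptide-loading protein TAPBP from 100 ± 3.37 to 69 ± 4.37 CPM. The immunoproteasome subunit PSMB10, on chromosome 16, fell from 23.1 ± 1.35 to 10.4 ± 1.36 CPM. HLA genes are polymorphic and similar in sequence, so their counts are uncertain.

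Stress and degradation lists were lower too. With each library left out, 7 of 11 calls held in the stress response list and 7 of 13 among autophagy and lysosome genes. In the unfolded protein and integrated stress response 11 of 29 members fell and 18 did not pass (12 falls as adjusted over the list alone; camera adjusted p = 4.6e-04; adjusted p = 0.33 with an estimated correlation). DDIT4, an inhibitor of mTORC1, fell from 262 ± 94.6 to 96.2 ± 12.6 CPM, with 214, 201 and 371 CPM in control replicates 1, 2 and 3. The median log2 ratio of control replicate 3 to the other 2 was 0.43 in this list and 0.54 for NF-kB targets. The phosphatase subunit PPP1R15A fell from 101 ± 6.32 to 56 ± 7.75 CPM, and HERPUD1, on chromosome 16, from 75.3 ± 14.2 to 29.6 ± 4.22 CPM. Of 29 autophagy and lysosome genes 12 fell and 1 rose (14 and 1 as adjusted over the list alone; camera adjusted p = 3.7e-04; adjusted p = 0.34 with an estimated correlation). The cathepsins CTSB and CTSD fell from 555 ± 16.3 to 239 ± 16.9 CPM and from 834 ± 72.8 to 348 ± 81.5 CPM, and MAP1LC3B, on chromosome 16, from 73.5 ± 12.9 to 34.6 ± 1.32 CPM. Of 12 tested histone messages 5 fell and 7 did not pass (6 falls as adjusted over the list alone; camera adjusted p = 0.013; adjusted p = 0.33 with an estimated correlation). H2AC6 fell from 32.4 ± 2.6 to 15.3 ± 2.37 CPM. Without knockout replicate 1 the set's adjusted p was 0.06, within a range from 4.6e-04 to 0.33 over its alternatives. Near-identical histone copies make these counts uncertain.

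Lists of proliferation genes were higher by small amounts. Of 30 genes of the G1 to S transition and DNA replication 6 rose and 24 did not pass, also as adjusted over the list alone, with 28 of 30 members above the controls (camera adjusted p = 1.5e-04; adjusted p = 0.78 with an estimated correlation). CDC25A, a phosphatase that activates cyclin-dependent kinases, went from 13.2 ± 4.24 to 24.5 ± 1.76 CPM (adjusted p = 0.031), with 16.3, 14.9 and 8.36 CPM in the controls. Control replicate 3 was the lowest control in this list, at a median log2 ratio of -0.68 to the other 2 controls. The CDC25A rise was a call lost without control replicate 2 and without knockout replicate 1, 2 or 3, with adjusted p up to 0.08. Of 30 genes of G2 phase and mitosis 11 rose and 19 did not pass (13 rises as adjusted over the list alone; camera adjusted p = 2.1e-04; adjusted p = 0.78 with an estimated correlation). The checkpoint kinase BUB1B rose from 76 ± 8.7 to 106 ± 8.89 CPM (adjusted p = 0.018), which was not past the threshold without control replicate 1 (0.055). None of the calls in these 2 lists (0 of 6 and 0 of 11) held in every fit that left out 1 library. Of 30 genes of ribosome biogenesis 8 rose and 22 did not pass (12 rises as adjusted over the list alone; camera adjusted p = 1.5e-04; adjusted p = 0.78 with an estimated correlation). Fibrillarin FBL rose from 260 ± 4.19 to 431 ± 46.6 CPM and BOP1 from 112 ± 11.7 to 196 ± 44 CPM, the only 2 of these 8 calls that held with each library left out. Of 44 cytosolic ribosomal proteins 8 rose and 1 fell (14 and 1 as adjusted over the list alone; camera adjusted p = 3.1e-04; adjusted p = 0.85 with an estimated correlation). In this list 0 of the 9 calls held with each library left out. The fall was RPL13, on chromosome 16, from 965 ± 70.9 to 731 ± 56 CPM, a call lost without control replicate 1, 2 or 3 and without knockout replicate 2 or 3, with adjusted p up to 0.082. In fry's directional test, which does not compare a list with other genes, none of these 4 lists passed (adjusted p = 0.21, 0.16, 0.16 and 0.11 in the order above). Knockout replicate 1 was highest in these lists. Its median log2 ratio to the controls was 0.62, 0.58 and 0.59 for the G1 to S, G2 and ribosome biogenesis lists, against 0.38, 0.22 and 0.16 in replicate 2 and 0.37, 0.22 and 0.17 in replicate 3.

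Cancer-testis and oncofetal genes were higher, with 3 of 13 tested members up and 1 down (4 and 1 as adjusted over the list alone; camera adjusted p = 3.1e-04; adjusted p = 0.34 with an estimated correlation). The call was lost with no filter on low counts (adjusted p = 0.12), within a range from 1.3e-05 to 0.34 over its alternatives. The controls of this list were spread about as widely as its median of 0.81, with a median log2 ratio of -0.82 for control replicate 3 against the other 2 and 0.62 for replicate 1 against 2. MAGEA6 rose from 6.01 ± 0.4 to 56.1 ± 6.87 CPM and MAGEA3 from 10.5 ± 0.85 to 22.5 ± 2.88 CPM. The near-identical sequences of this pair make the split between them uncertain. LIN28B, a blocker of let-7 maturation, rose from 2.41 ± 0.763 to 13.8 ± 1.14 CPM (log2 fold change 2.51, SE 0.25, adjusted p = 5.5e-04). The imprinted transcript H19 fell from 2.58 ± 0.888 to 0.302 ± 0.198 CPM.

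**Figure D3:**
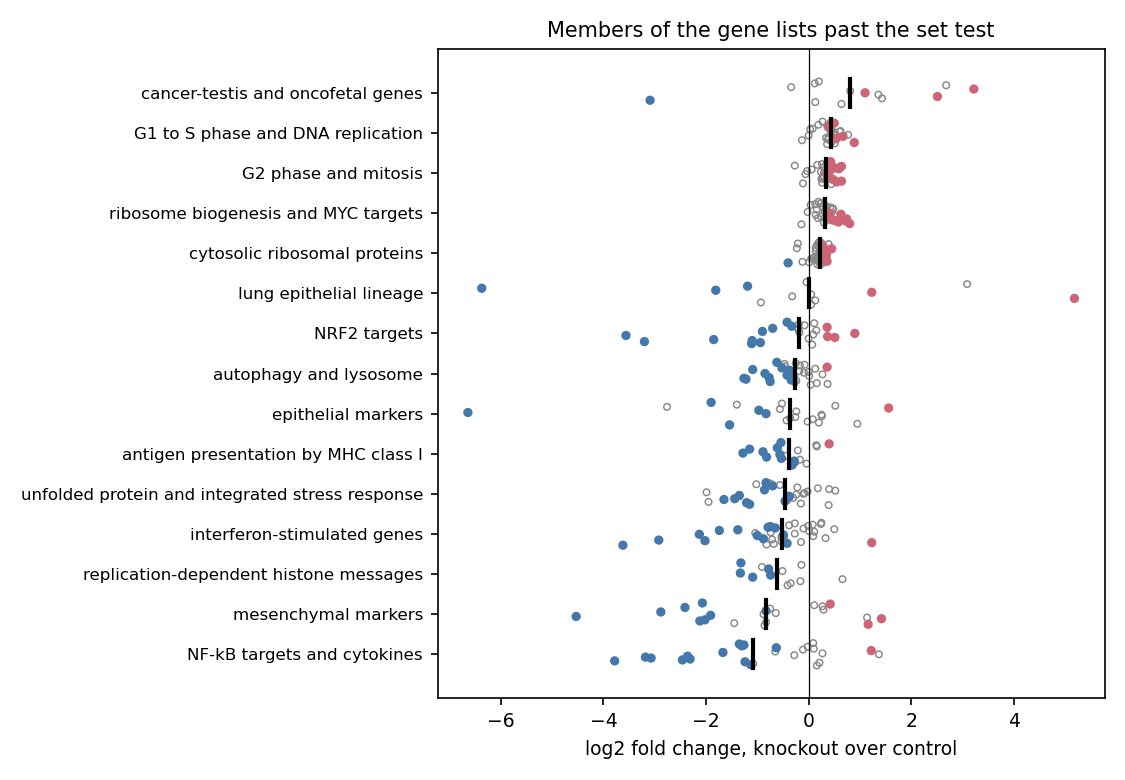
Log2 fold change, knockout over control (x axis), of each tested member of the 15 lists past the set test (rows), with filled points for genes past an adjusted p of 0.05, open points for the others and bars for the median of each list. Medians ran from -1.08 for NF-kB targets and cytokines to 0.81 for cancer-testis and oncofetal genes, and 0 lists passed with an estimated correlation.

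The lists closest to the protein's known partners did not pass camera as sets. Of 31 messages reported as bound by IGF2BP proteins 8 rose and 6 fell (9 and 6 as adjusted over the list alone; camera adjusted p = 0.24), and 4 of the 14 calls held with each library left out. Cyclin D1 CCND1 rose from 281 ± 22 to 434 ± 50.2 CPM and the kinase CDK6 from 105 ± 1.99 to 157 ± 22.7 CPM, next to LIN28B above. Of 20 writers, erasers and readers of N6-methyladenosine 1 rose and 3 fell, also as adjusted over the list alone (camera adjusted p = 0.94), with a median log2 fold change of 0.02 against a mean of -0.04. The demethylase FTO, on chromosome 16, fell from 56.3 ± 1.58 to 35 ± 3.15 CPM. The methyltransferase METTL3 went from 55.4 ± 9.85 to 78.5 ± 0.915 CPM (adjusted p = 0.029), a call lost without control replicate 1 and without knockout replicate 2 or 3, with adjusted p up to 0.081. In insulin and IGF signalling 3 of 23 genes rose and 9 fell (5 and 10 as adjusted over the list alone; camera adjusted p = 0.056). The receptor substrates IRS2 and IRS1 fell from 61.1 ± 4.68 to 25.6 ± 4.52 CPM and from 233 ± 10.4 to 136 ± 15.4 CPM. That set passed without control replicate 2 (0.038), without knockout replicate 1 (0.0049) and without knockout replicate 3 (0.043). It also passed with no filter on low counts (0.0033), with quantile normalization (0.045), with limma-voom (0.039) and on FPKM (0.04), the last 2 chosen after the data were seen. Its camera range was 0.0033 to 0.33, and fry's directional test called the set lower (adjusted p = 0.0011).

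Metabolic lists went both ways and did not pass. Of 30 glycolysis and hypoxia genes 4 rose and 6 fell (5 and 7 as adjusted over the list alone; camera adjusted p = 0.54, and 0.024 without knockout replicate 1, in a range from 0.024 to 0.9). The lactate transporter SLC16A3 fell from 150 ± 10.4 to 21.9 ± 3.64 CPM and the glucose transporter SLC2A3 rose from 17.5 ± 1.37 to 59.8 ± 1.75 CPM. Of 26 genes of amino acid and one-carbon metabolism 1 rose and 5 fell (3 and 5 as adjusted over the list alone; camera adjusted p = 0.36). Argininosuccinate synthase ASS1 fell from 70.1 ± 12.4 to 7.22 ± 1.13 CPM. Of 22 ferroptosis and iron genes 4 rose and 6 fell (4 and 8 as adjusted over the list alone; camera adjusted p = 0.76). ACSL4, an acyl-CoA ligase, fell from 170 ± 13.4 to 84.7 ± 0.48 CPM. Of 39 nuclear genes of oxidative phosphorylation 2 rose and 2 fell (1 and 2 as adjusted over the list alone; camera adjusted p = 0.86), both falls, UQCRC2 and COX4I1, on chromosome 16. Of 13 mitochondrially encoded messages 0 were called in edgeR, adjusted over all genes or over the list alone. At an unadjusted p under 0.05 there was 1, DESeq2 called 1 and limma-voom 0. MT-ATP8, with the smallest p, was at 1190 ± 64.3 and 1480 ± 172 CPM. Of 23 cholesterol genes 1 rose and 1 fell, also as adjusted over the list alone (camera adjusted p = 0.94), with a median of 0.03 and a mean of -0.08. The fall, MVD, is on chromosome 16.

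Of the signalling lists, WNT targets and regulators held 5 rises and 3 falls of 17 (6 and 3 as adjusted over the list alone; camera adjusted p = 0.98), with the ligand WNT5A falling from 23.5 ± 1.06 to 1.34 ± 0.327 CPM. TGF-beta targets held 3 rises and 5 falls of 21 (4 and 7; camera adjusted p = 0.58), with the receptor TGFBR2 falling from 466 ± 11.3 to 255 ± 17 CPM. MAPK output held 3 rises and 5 falls of 21 (7 and 5; camera adjusted p = 0.94), with the phosphatase DUSP4 falling from 299 ± 48.4 to 162 ± 16.4 CPM. YAP and TEAD targets held 3 rises among 20 (2; camera adjusted p = 0.36) and apoptosis regulators 3 rises among 26 (3; camera adjusted p = 0.63), and 0 of 3 calls in each held with every library left out. The counts in parentheses for each of these lists are those adjusted over the list alone. Among neuroendocrine and neuronal genes 2 rose and 3 fell of 11 (3 and 3 as adjusted over the list alone; camera adjusted p = 0.76). Synaptophysin SYP rose from 1.22 ± 0.266 to 6.5 ± 1.51 CPM and SNAP25 fell from 72.6 ± 3.13 to 29.9 ± 8.62 CPM. Markers of other cell types did not pass camera as sets. In fry's directional test fibroblast markers (adjusted p = 0.033) and blood and endothelial markers (0.028) were called lower. That test called 293T markers higher (0.0011). Fibroblast markers held 1 rise and 1 fall of 10 (1 and 2 as adjusted over the list alone; camera adjusted p = 0.76), neither kept with every library left out. Of 5 blood and endothelial markers 3 fell, also as adjusted over the list alone (camera adjusted p = 0.069). That set passed without control replicate 1 (0.042), without knockout replicate 3 (0.03) and with quantile normalization (0.047), in a camera range from 0.03 to 0.34. Markers of 293T, the cells that made the virus, held 3 rises and 1 fall of 11 (3 and 1 as adjusted over the list alone; camera adjusted p = 0.057). The set passed without control replicate 3 (0.032) and with a mean count of at least 100 (0.038), in a camera range from 0.032 to 0.33. CHD5 rose from 1.73 ± 0.398 to 6.05 ± 1.03 CPM and INA from 27.6 ± 1.39 to 41.6 ± 2.14 CPM.

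Because single-cell colonies had been expanded, each chromosome was also tested as a set. Chromosome 16 was lower as a whole, with 374 of its 948 tested genes down and 6 up and a median log2 fold change of -0.49 (camera adjusted p = 7.6e-16; adjusted p = 0.0026 with an estimated correlation). The median of its genes against the controls was -0.49 in each of the 3 knockout libraries. This chromosome held 4.7% of the tested genes and 16.2% of the falls. Chromosome 19 was higher, with 185 of 1296 genes up and 77 down and a median of 0.16 (camera adjusted p = 0.036; adjusted p = 0.16 with an estimated correlation). Its call was lost without control replicate 1 (0.081), control replicate 2 (0.076), knockout replicate 2 (0.076) and knockout replicate 3 (0.059), in a range from 0.0017 to 0.16. A fit without the genes of chromosomes 16 and Y was chosen after the data were seen. In it 3453 of 19161 genes passed, 1488 up and 1965 down. All 15 lists above remained past the threshold of camera at the preset correlation. This fit kept other chromosomes with shifted windows, so it does not separate the lists from such regional shifts.

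**Figure D4:**
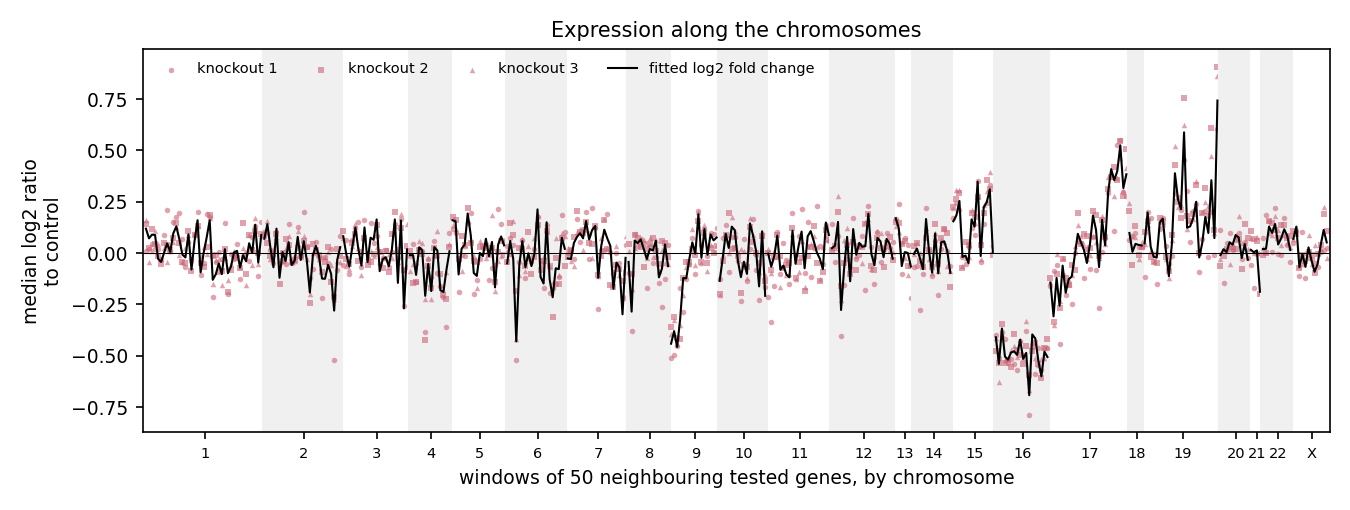
Median log2 ratio to the controls (y axis) in windows of 50 neighbouring tested genes, in order along chromosomes 1 to 22 and X (x axis), with a symbol for each knockout library and a line for the fitted log2 fold change. The 18 windows of chromosome 16 lie between -0.69 and -0.37, and windows on 9, 15, 17 and 19 also leave 0.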

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

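Fits on FPKM, with limma-voom and TMM, and without chromosomes 16 and Y were chosen only after the data were seen. The alternative with another pseudocount applied to tables of FPKM alone and was not run. For 157 named genes, 2197 of 2437 values kept their side of the threshold, 237 were no longer past it and 3 came to pass it. A change of direction with either fit past the threshold was seen for 0. For the lists these numbers were 564, 24, 20 and 0 of 608 values. Changes of direction with neither fit past the threshold were not counted. They did occur among lists that did not pass. WNT targets, for example, were higher in camera with all genes and lower without chromosomes 16 and Y. Calls numbered 2858 with no filter on low counts, where the rises were 1055 and more genes were tested (33982), 4009 with a mean count of at least 100, 3946 with DESeq2-type size factors, 5209 with DESeq2, 4682 with quantile normalization (49.6% lower), 4188 with limma-voom and TMM, and 3611 on FPKM (49.7% lower). Against a minimum fold of 1.5 there were 930 calls, 259 higher and 671 lower, and IGF2BP3 at a log2 fold change of -0.91 was no longer past the threshold (adjusted p = 0.25); this test asks for a larger change by construction and gives no list values. With 1 library left out, calls ranged from 2183 to 5338, rises from 773 to 2274, falls from 1410 to 3064, the IGF2BP3 log2 fold change from -1.2 to -0.75 and chromosomes past the threshold from 1 to 2; the lowest counts came without control replicate 1, the highest without knockout replicate 1, and the cause was not tested. Lists past the threshold were 0 and chromosomes 1 with an estimated correlation. Calls were lost also where this estimate lay below the preset 0.01, as for mesenchymal markers (-0.017), histones (-0.021) and NRF2 targets (0.007). With an estimated correlation camera uses the few residual degrees of freedom of the 6 libraries, which raises p-values by itself. Members moving together therefore do not account for every loss. Fry called 16 lists in its directional test, 11 of them also called by camera. The others were insulin and IGF signalling (0.0011), 293T markers (0.0011), drug transport and aldehyde metabolism (0.0027), blood and endothelial markers (0.028) and fibroblast markers (0.033). The 4 lists of the cell cycle, ribosome biogenesis and ribosomal proteins were not past it (0.11 to 0.21). Its mixed test, which counts changes in either direction, called 34. Chromosomes past the threshold were 3 with a mean count of at least 100, with quantile normalization, with limma-voom and on FPKM. The replicate numbers did not pair the libraries: correlations of same-numbered deviations were 0, -0.07 and -0.06, and 0 of 3 controls correlated best with their own number. With the replicate block 3001 genes passed, 1146 higher and 1855 lower, and the sets of insulin and IGF signalling (adjusted p = 0.04) and of blood and endothelial markers (adjusted p = 0.044) passed. Of simulated 1.5-fold changes 12% were recovered at this depth, this number of libraries and the trended dispersion, and which of these is the limit was not tested.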

Other observations

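The tests on knockout replicate 1, the matched genes and the KEGG pathways were chosen after the values they concern had been seen. Of 301 KEGG pathways annotated in the table with 15 to 300 tested genes, 47 passed camera, 40 lower and 7 higher, and 0 with an estimated correlation (29 at an unadjusted p under 0.05). The lowest p was that of genes annotated to Staphylococcus aureus infection, of which 16 of 37 fell (adjusted p = 3.0e-16; adjusted p = 0.17 with an estimated correlation). In ascorbate and aldarate metabolism 11 of 21 genes fell and 0 rose (adjusted p = 9.7e-13; adjusted p = 0.12 with an estimated correlation), and this list holds many UGT1A members that share exons. In arachidonic acid metabolism 13 of 33 fell and 1 rose (adjusted p = 3.7e-10; adjusted p = 0.17 with an estimated correlation), in steroid hormone biosynthesis 13 of 37 fell and 3 rose (adjusted p = 3.9e-09; adjusted p = 0.12 with an estimated correlation), and in the complement and coagulation cascades 22 of 61 fell and 6 rose (adjusted p = 2.0e-08; adjusted p = 0.3 with an estimated correlation). Higher pathways were led by the ribosome, with 18 of 135 up and 6 down (adjusted p = 3.5e-05; adjusted p = 0.81 with an estimated correlation), and RNA transport, with 27 of 154 up and 9 down (adjusted p = 6.1e-04; adjusted p = 0.81 with an estimated correlation). The other 5 were DNA replication, the spliceosome, ribosome biogenesis, the proteasome and the cell cycle. A gene can be annotated to several pathways, so the pathways that passed are not separate results. Their overlap was not examined.

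Some messages of high or low level, also chosen after their values were seen, describe the cells of both groups. ALDH1A1, an aldehyde dehydrogenase, ranked 4 of all genes by mean CPM and lay between 6970 and 8610 CPM in the 6 libraries. AKR1B10 ranked 20 and fell from 4070 ± 75.7 to 2110 ± 506 CPM (adjusted p = 0.0061). CDKN2A lay between 0 and 0.57 CPM.

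Chromosome 16 was lower in the knockout libraries, and the trend on GC content and gene length was small (-0.01 to 0.07 from its 5th to its 95th percentile), so that its removal moved the median of chromosome 16 only from -0.5 to -0.51, while 932 matches of like GC content and length on other autosomes had a median of 0.03 (95% interval 0.01 to 0.07), which argues against that bias. In the knockout library whose total lay within the range of the controls the median of chromosome 16 was -0.49, which argues against depth. Of the windows of 50 neighbouring genes on this chromosome, 100% had a median below -0.2, against 15 of 360 windows (4.2%) on other autosomes, a pattern consistent with a copy-number difference between the cell colonies as a hypothesis. Runs of neighbouring windows on other chromosomes also moved together, with 4 windows at the start of chromosome 9 between -0.46 and -0.32 and 7 at the end of chromosome 17 between 0.30 and 0.53. All knockout libraries carry the pattern and no control does, so an effect of the knockout on these genes stays open and untested. Which share of the other changes came with the colonies stays open too. On the Y chromosome 20 of 25 tested genes rose and 0 fell. The 20 went from a median of 0.029 CPM, below the floor, to 2.91 CPM. Such a rise across a chromosome argues against a knockout effect on single genes there, though DNA was not measured.

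Knockout replicate 1 stood apart from the other 2 knockout libraries, with a chi-square per degree of freedom of 98.1 and 106 against them, compared with 14.8 between those 2. A mixture with control cells would need one share for all genes, but 99 genes high in the controls needed a median of 1.6% (95% interval 0.2 to 3.6) and 19 genes high in replicates 2 and 3 needed 55.3% (27.8 to 71.9), a difference of 53.7 percentage points, which argues against it. After all 3 were thinned to the smallest total the chi-square against replicate 2 was still 6.42 times that between replicates 2 and 3, which argues against depth. A separate colony or culture stays open, since the labels do not give either, and no biological explanation was tested.

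Of the 10 splits of the 6 libraries into 3 against 3, the real one gave 3963 calls and the highest other gave 0. Each of the other splits mixed controls and knockouts in both groups, so the difference between them widened the spread within groups. Few calls were thus built into those splits, and the 0 does not measure false calls. With 10 splits the share cannot fall under 0.1, so these splits are too few for a share under 0.05.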
